A study of Caenorhabditis elegans with 2 samples.

How the data were processed

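The series measured where a tagged zinc finger protein, ZTF-26, sat on the genome of the nematode Caenorhabditis elegans, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Per the labels, the worms carried a transgene that expresses ZTF-26 joined at its C terminus to GFP and FLAG, and an anti-GFP antibody pulled down the fusion protein with the sonicated chromatin bound to it. Whole young adult worms of mixed sex were collected 56 hours after synchronization as starved L1 larvae. The labels name 2 biological replicates, numbers 3 and 4, which form 1 group. A control library and libraries of other factors were not analysed here.

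The data were peak lists on the builds ce10 and ce11. Per the deposited list of files, the authors called a list of peaks and background from each replicate's alignment against a control alignment, called a pooled list from both alignments together, and derived an optimal list of reproducible peaks (irreproducible discovery rate, IDR) from these. The peak caller, the aligner and the IDR threshold were not given in the sources used here. Each peak in the deposited lists has a signal value, which is the authors' own value for that peak. Its scale was not given in the sources used here, so signal was used only to rank, describe and filter peaks and to compare the replicates across the same peaks. Each peak in the deposited lists also has a −log10 q-value and the position of its summit. All peaks of the optimal list carried a single −log10 q-value of 3.63, so the q-value could not rank them. The optimal list was tested against the pooled list and held exactly the 1929 pooled peaks with the highest signal on ce11. The candidate list of replicate 3 held exactly 30000 peaks on both builds, a round number, so the length of that list was not read as a measurement. The files give no read counts, so the depth of each library is unknown, and no interval that needs depth was computed.

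The optimal list on ce11 was the main set, and the 26304 pooled candidates outside it, called from the same reads, were the lower-ranked comparison set. Gene positions came from the WBcel235 annotation of Ensembl release 115 and sequences from the reference genome of that build, used with the ce11 lists alone. A promoter window ran from 1000 bp upstream to 500 bp downstream of the 5' end of an annotated transcript. A summit was given 1 feature, with tRNA, snoRNA and other non-coding RNA genes kept apart from exons, introns, untranslated regions and intergenic sequence. Coordinates are on ce11 and 1-based.

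The overlap of the replicates was the share of replicate 3's 1929 strongest peaks that shared at least 1 bp with the 1929 strongest of replicate 4. It was set against 1000 random placements of replicate 3's peaks on the same chromosomes, in a one-sided permutation test whose smallest possible p is 0.000999. Replicate signal was compared by Spearman's rho across optimal peaks, without a p-value, since peaks are not independent replicates. Shares of peaks were compared by two-sided Fisher's exact tests, with 95% exact Clopper-Pearson intervals. Those intervals and p-values treat peaks or genes as independent and cover counting error only, not the variation between worm cultures. For 36 gene lists, fixed by gene name or gene class before the data were examined, genes with an optimal summit in their promoter window were counted and compared with the other genes of a background. The background was all 19973 protein-coding genes or, for lists of non-coding genes, the 29399 annotated genes other than piRNA genes and pseudogenes. These tests were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment at 0.05. Sequence words of 7 bases (7-mers, both strands together) were compared between the 101 bp around each summit and a window of the same length 300 bp to 1 side, by McNemar's exact test. A 7-mer had to pass at an adjusted p of 0.05 on the 868 peaks of chromosomes I, III and V, and then again on the 1061 held-out peaks of II, IV and X.

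The genes named in the text followed a rule fixed before the data were examined. It took the 25 optimal peaks of highest signal, each named by the nearest 5' end of a protein-coding gene. For each list past its threshold it took up to 4 members with the strongest peaks, and ztf-26 and unc-119 were added whatever their values. Names outside this rule are marked where they appear.

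The list and 7-mer tests were tested on simulated data. A 5-fold excess was recovered in 100% of 50 simulations for the ribosomal protein list and in 98% for the chaperone list. Of lists without a planted excess, 0.121% were called. Each simulated gene drew its peak independently, whereas real genes can share a peak. That percentage is therefore not the rate of false calls for lists whose genes share peaks. A 7-mer planted in 6% of summit windows was recovered in 80% of 20 simulations, with a mean of 0.25 other 7-mers called per simulation. The simulated windows were placed at random, whereas real summits are richer in G and C than their flanks (46.3% against 35.7%). That mean is therefore not the rate of false calls among the real words. Alternatives tried were the 965 optimal peaks of highest signal in place of all 1929, each replicate alone, the ce10 build, other overlap rules, other promoter windows, peak midpoints, a gene background limited to genes with a candidate summit, and other word lengths and windows. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.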

Results

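ZTF-26, a zinc finger protein tagged with GFP, was mapped by anti-GFP ChIP-seq in whole young adult worms, in 2 biological replicates of 1 group. The optimal list held 1929 reproducible peaks on ce11, which merged into 1833 regions covering 770951 bp, or 0.769% of the genome. Peak signal, the authors' value for each peak, ran from 90.2 to 1104 with a median of 131. The candidate lists were longer, with 28233 peaks in the pooled list, 30000 in replicate 3 and 20373 in replicate 4. The depth of the libraries is unknown, since the files give no counts.

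The strongest peak in the pooled list and in each replicate lay at III:3867314-3867766, in intergenic sequence with its summit 297 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Its signal was 1104 in the pooled list, 715 in replicate 3 and 389 in replicate 4. All 25 top peaks ranked 33 or better in replicate 3 and 40 or better in replicate 4. Of replicate 3's 1929 strongest peaks, 1359 (70.5%) overlapped a peak among the 1929 strongest of replicate 4, against a mean of 31.1 and a maximum of 52 in 1000 random placements (permutation p = 0.000999, one-sided, the smallest the placements can give). In the other direction, 1390 of 1929 (72.1%) were shared. Of the optimal peaks, 1918 overlapped a candidate of any rank in both replicates, 1347 (69.8%) overlapped the top lists of both, and 35 overlapped neither top list. Across optimal peaks, which are not independent replicates, signal in the replicates gave a Spearman's rho of 0.635 and a Pearson's r of 0.75 on the log2 scale. The median ratio of replicate 3 to replicate 4 was 1.73, and the log2 ratio had an SD across peaks of 0.48, a 1.40-fold spread. This describes how far the replicates differed at the same peak. The error of a difference between peaks in pooled signal was not measured.

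**Figure D1:**
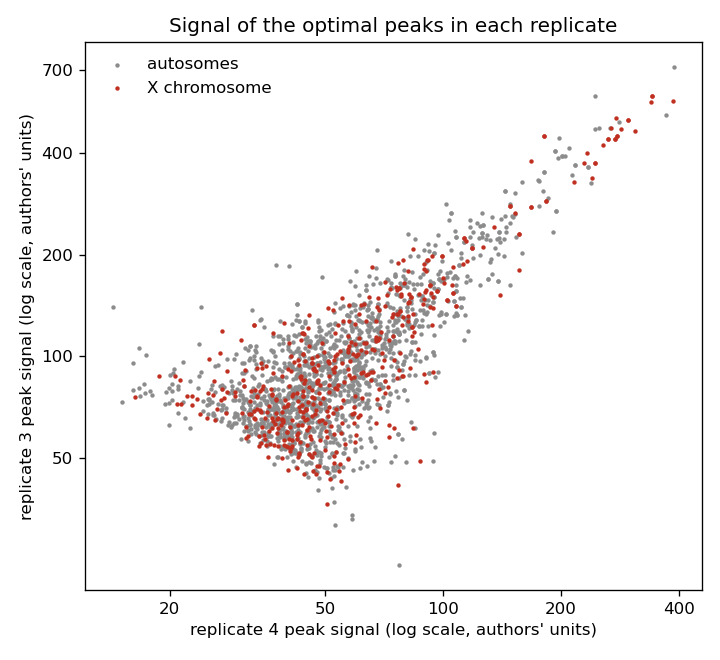
Signal of each optimal peak in replicate 4 (x axis, log scale, authors' units) and replicate 3 (y axis, log scale, authors' units), with autosomal peaks in grey and X-linked peaks in red. The ranks were correlated with a rho of 0.635, and the top peak, upstream of rpl-3, stood highest in both replicates at 715 and 389.

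The top 25 peaks were near promoters on the autosomes and mostly away from them on X. On the autosomes, 7 of 10 top peaks had their summit in the promoter window of a protein-coding gene, with a median distance of 463 bp to the nearest 5' end. After rpl-3, those in promoter windows included the peak nearest tasp-1 at III:10759080-10759451 (signal 831, 65 bp upstream), that between Y17G9B.5 and the ribosomal protein gene rpl-20 at IV:4749903-4750234 (signal 769), that upstream of rpl-15 at IV:654777-655099 (signal 737, 349 bp upstream), and that upstream of set-16, a histone methyltransferase gene, at III:13643589-13643910 (signal 729, 171 bp upstream). The peak named by egg-5, at I:4171961-4172600 (signal 600), had its summit 20 bp upstream of sls-2.4, a gene for a spliced leader RNA. The peaks nearest ppfr-1 (signal 883, inside an annotated non-coding RNA gene), cmd-1 (calmodulin, signal 715), T04C4.3 (signal 632) and tag-340 (signal 626) completed the autosomal set. Several of these summits also lay in the window of a further gene, named here outside the rule. Among these genes were K01G5.10 for the tasp-1 peak, K11H12.8 for rpl-15, drr-2 for set-16 and nhl-2 for tag-340.

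On X, 2 of 15 top peaks had their summit in such a window, those near nspc-17 and ftt-2 (a 14-3-3 protein gene), fewer than on the autosomes (Fisher's exact p = 0.009, a comparison chosen after the values were seen). Of the 15, 13 lay more than 1000 bp from any protein-coding 5' end, with a median distance of 2550 bp over the 15, and 11 of the 15 were intergenic and 2 intronic. The strongest was at X:11093931-11094437 (signal 948), 3985 bp from the 5' end of W02H3.3. It was followed by an intronic peak at X:6296286-6296855 (signal 925), 3393 bp upstream of cest-16, and by the nspc-17 peak at X:14525562-14526177 (signal 908). The peak at X:8036126-8036905 (signal 797) lay 4848 bp upstream of xol-1, the switch gene of sex determination and dosage compensation, and 220 bp from a tRNA gene. The other X-linked top peaks, nearest K02D3.1, F20B6.9, C41A3.2, ZK899.6, Y41G9A.17, F19H6.5, F55G7.5, F22H10.2, fbxb-58, gtr-1 and ftt-2, had signals from 612 to 782.

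X held more of the optimal peaks than of the weaker candidates. Of 1929 optimal peaks, 463 (24.0%, 95% exact interval 22.1 to 26) were on X, against 4383 of 26304 lower-ranked candidates (16.7%), an odds ratio of 1.58 (two-sided Fisher's exact p = 2.5e-15). X makes up 17.7% of the genome. The share was 60% of the top 25 peaks, 29% of the top 100 and 25.2% of the top 500. Among autosomal peaks alone, none of the 5 autosomes passed the test, with the lowest adjusted exact p at chromosome I (17.3% of optimal and 19.8% of lower-ranked peaks, 0.114 after adjustment and 0.023 before). Each replicate alone gave an X share of 23.3% or 23.4% of its top list.

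**Figure D2:**
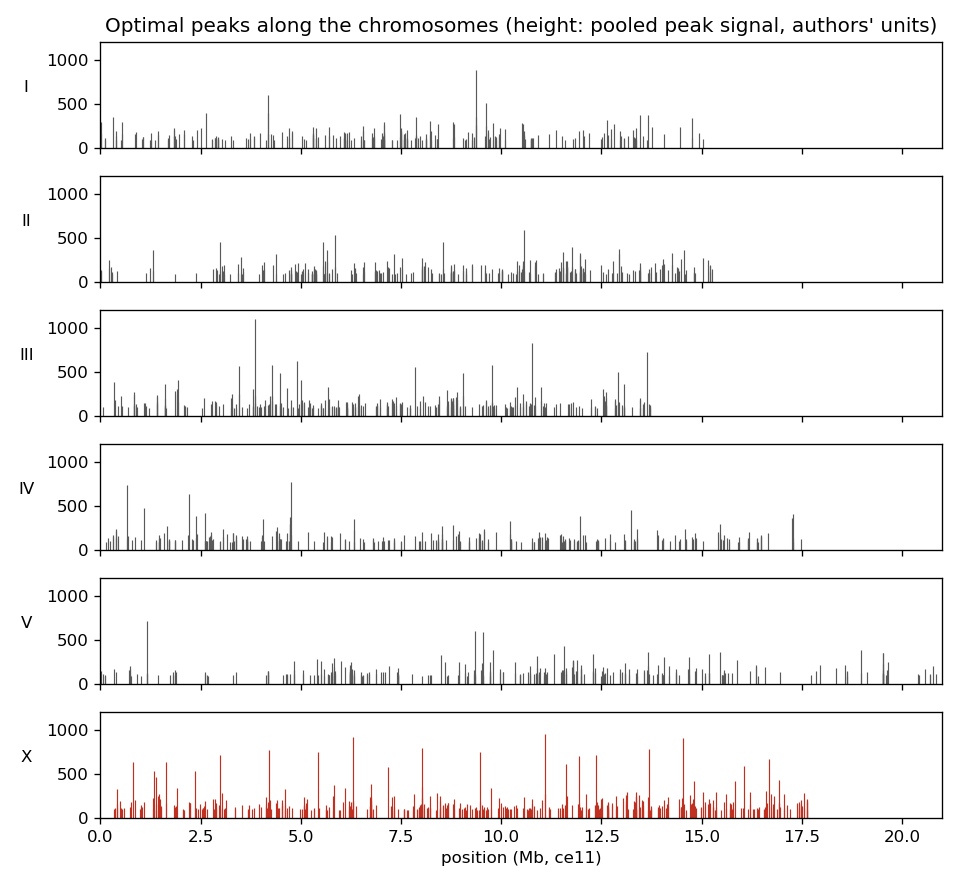
Optimal peaks along the 6 chromosomes (x axis, position in Mb on ce11), with the height of each line giving the pooled peak signal in the authors' units and X in red. The top 25 peaks include 15 on X, spread along its length, and the highest single peak, at 1104 on III.

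Peaks lay at promoters more often than weaker candidates did, and seldom in coding exons. The summit of 983 optimal peaks (51%, 48.7 to 53.2) was in the promoter window of a protein-coding gene, against 37.6% of lower-ranked candidates (odds ratio 1.73, Fisher's exact p = 9.9e-31) and 31.3% of random placements (highest 34.7%, permutation p = 0.000999, the smallest possible). The promoter share was 54.3% on the autosomes and 40.4% on X, and these differed (odds ratio 0.57, Fisher's exact p = 2.1e-07), but the background differed the same way, with 38.5% and 32.9% of lower-ranked candidates and 33.0% and 26.8% of random placements. On X the optimal share was above that of the lower-ranked candidates (odds ratio 1.38, Fisher's exact p = 0.0016), by less than on the autosomes (odds ratio 1.90), with a ratio of these odds ratios of 0.726 (95% normal interval 0.581 to 0.907, chosen after the values were seen). By annotation, 52.3% of summits were intergenic, 20.9% intronic, 7.93% in coding exons, 3.37% in 5' untranslated regions and 1.40% in 3' untranslated regions. Coding exons took 30.7% of the lower-ranked summits and 24.4% of random ones, an odds ratio of 0.195 for optimal against lower-ranked peaks (adjusted exact p = 7.9e-123 over 8 features).

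Genes for transfer RNAs were the feature with the largest excess over random placements. The summits of 103 peaks (5.34%) lay inside a tRNA gene, 110 times the share of random placements (0.0487%) and above the 0.395% of lower-ranked candidates (adjusted exact p = 2.1e-63). A further 12 summits (0.622%) lay inside genes for small nucleolar RNAs, which guide RNA modification, and 157 (8.14%) inside other non-coding RNA genes. Counted within 100 bp of a gene, a measure chosen after the values were seen, tRNA genes took 210 peaks (10.9%) and snoRNA genes 72 (3.73%), against 0.882% and 0.297% of lower-ranked candidates.

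Of 36 lists, 15 passed the threshold, 11 with more genes with a peak than the background and 4 with fewer. Of 612 tRNA genes, 270 (44.1%) had an optimal summit in their promoter window, against 6.69% of other genes (odds ratio 11.0, adjusted exact p = 1.1e-139), and 211 distinct peaks lay behind them. By the strongest summit in each window, the leading genes were a pair on X at 8036685-8036757 and 8037507-8037578 (signals 797 and 357). With them was a convergent pair on V at 15465086-15465158 and 15465225-15465296 (signal 366 for 1 shared peak, its summit downstream of both 5' ends). The X signals come from separate summits in the interval X:8036126-8036905, that of the top peak nearest xol-1. The first summit lay 292 bp downstream of the 5' end of the first tRNA gene. The second, at 8036669, lay 838 bp upstream of the second gene and was closer to the first. Only the window rule links it to the second gene. For 79 of the 270 genes the peak was also in the window of a protein-coding gene. Of 346 snoRNA genes, 98 (28.3%) had a peak (odds ratio 5.08, adjusted exact p = 1.7e-30), through 93 distinct peaks, and for 48 the peak was also in a protein-coding window. The strongest snoRNA example shows this, since K11H12.12 and K11H12.13 share the rpl-15 peak, and C06A1.9 (signal 596) and T27A8.8 (signal 594) follow.

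Spliced leader RNAs, which are joined to the 5' ends of many worm mRNAs, had a peak at 12 of 30 genes (40.0%, adjusted exact p = 3.3e-06), through 9 distinct peaks, led by sls-2.4 (signal 600), sls-2.1 (533), sls-2.2 (456) and sls-2.9 (211). The list of small nuclear RNA genes passed with 22 of 129 genes (17.1%, adjusted exact p = 0.00095). It contains all 30 spliced leader genes, and without them 10 of 99 genes (10.1%) had a peak, which did not differ from other genes (Fisher's exact p = 0.33). Its call also ended among the 965 strongest peaks (adjusted exact p = 0.060). Copies of tRNA, snoRNA and spliced leader genes can be near-identical and share reads, so which copy a peak belongs to is uncertain.

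Genes for ribosomal proteins, translation factors, chaperones and the respiratory chain carried peaks more often than the 5.69% of all protein-coding genes (1136 of 19973), whereas aminoacyl-tRNA synthetases, at 1 of 31, did not pass the test. Of 81 ribosomal protein genes, 33 (40.7%, 29.9 to 52.2) had a peak, an odds ratio of 11.7 (adjusted exact p = 1.8e-19), with 30 in replicate 3's own top list and 28 in replicate 4's. After rpl-3, rpl-20 and rpl-15 the strongest was rpl-35 (III:7854548-7854831, signal 556). Of 41 translation factor genes, 9 (22%, adjusted exact p = 0.0012) had one, led by iff-2, an eIF5A gene, (signal 458, 68 bp upstream), the elongation factor genes eef-1A.2 (272) and eef-1A.1 (195), and the initiation factor gene eif-3.C (230). Of 59 chaperone genes, 17 (28.8%, adjusted exact p = 1.2e-07) had one, led by cct-8 of the cytosolic chaperonin (signal 481), the HSP70 gene hsp-1 (407), the mitochondrial chaperonin gene hsp-60 (359) and dnj-13 (347). Of 47 respiratory chain genes, 15 (31.9%, adjusted exact p = 1.6e-07) had one, led by cox-5A (signal 500), atp-1 (324, summit at its annotated 5' end), cox-5B (283) and nduf-2.2 (247).

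Genes of the endomembrane and lysosomal system were also above the background. Peaks lay at 20 of 100 membrane trafficking genes (20%, adjusted exact p = 3.3e-06), led by the translocon genes sec-61.B (signal 382) and sec-61.G (317), the late endosomal GTPase gene rab-7 (309) and vps-60 (247). They lay at 6 of 20 genes of the vacuolar proton pump (30%, adjusted exact p = 0.0018), with vha-12 (181), vha-1 (156), vha-8 (142) and vha-13 (135) the strongest. They lay at 7 of 32 autophagy genes (21.9%, adjusted exact p = 0.0047), among them epg-7 (248), lgg-2 (209), hlh-30, a transcription factor gene of lysosome and autophagy control (169), and atg-9 (168). Against only those genes that had a candidate summit of any rank, the calls of the translation factors (adjusted exact p = 0.091), the proton pump (0.091) and the autophagy genes (0.175) ended. The calls of the tRNA, snoRNA, ribosomal protein, chaperone, respiratory chain and trafficking lists did not end there, but their odds ratios fell, to 5.42, 3.44, 5.12, 4.53, 3.99 and 2.72.

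Large families of environmental and sensory genes carried few peaks. Chemoreceptor genes had a peak at 8 of 1308 (0.612%, odds ratio 0.0957, adjusted exact p = 6.3e-23), with the strongest at srh-2 (signal 202), sre-23 (194), srh-269 (194) and srh-17 (173). Innate immune effector genes had 3 of 353 (0.85%, adjusted exact p = 1.5e-05), clec-126 (280), clec-221 (114) and spp-26 (105), the last with its summit in a tRNA gene. F-box, MATH and BTB genes had 8 of 412 (1.94%, adjusted exact p = 0.0011), with fbxb-85 (220), fbxa-83 (167), fbxb-58 (166, a weaker summit in the interval of the top peak named above) and fbxb-72 (158) the strongest. Detoxification genes had 2 of 185 (1.08%, adjusted exact p = 0.0082), gst-27 (252) and gst-9 (125). Few chemoreceptor genes had a candidate of any rank, and among those 157 genes 8 (5.10%) had a peak against 14.4% of other genes, an odds ratio of 0.320 (adjusted exact p = 0.0018). The detoxification call ended without replicate 3 (4 genes, adjusted exact p = 0.110), the F-box call ended against genes with a candidate summit (adjusted exact p = 1), and both ended among the 965 strongest peaks (adjusted exact p = 0.085 and 0.108).

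The other 21 lists did not pass. Cuticle collagens had a peak at 17 of 173 genes (9.83%, adjusted exact p = 0.067) and passed without replicate 3 (18 genes, adjusted exact p = 0.024). Splicing factors (6 of 50, adjusted exact p = 0.13), cell cycle and replication factors (7 of 61, 0.17) and microRNA genes (27 of 261, 0.18) passed with a window reaching 2000 bp upstream (adjusted exact p = 0.0095, 0.048 and 0.021). The proteasome had 4 of 33 genes with a peak and histones 4 of 81. The lists of tissue markers had a peak at 1 of 39 intestinal, 1 of 31 muscle contractile, 1 of 23 neuronal, 3 of 48 germline and P-granule and 1 of 44 meiosis genes. Of 31 major sperm protein genes and 20 rRNA genes none had an optimal peak, and of 6 vitellogenin genes 1 did. A candidate of any rank was listed at 6 of the major sperm protein genes, 1 of the rRNA genes and 25 of the histone genes, against 73 of 81 ribosomal protein genes. How far repeated copies limit calling in these families was not tested. Regulators had 20 of 269 nuclear hormone receptors, 4 of 37 bHLH factors, 2 of 90 homeobox factors and 2 of 24 other ztf genes. Lipid metabolism enzymes had 4 of 109, and neuropeptides and insulins 4 of 143. Several small counts moved with the replicate used, without the list passing. Neuropeptides and insulins had 7 genes without replicate 4 and 9 without replicate 3, and the last share (6.29%) was above the background. Without replicate 3, lipid metabolism enzymes had 6, muscle contractile and intestinal genes 2 each and homeobox factors 1. Without replicate 4, meiosis genes had 2, other ztf genes 1, and neuronal and vitellogenin genes 0. Aminoacyl-tRNA synthetases had 2 with either replicate alone. The small lists leave wide intervals, so an excess in them may not have been detectable.

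**Figure D3:**
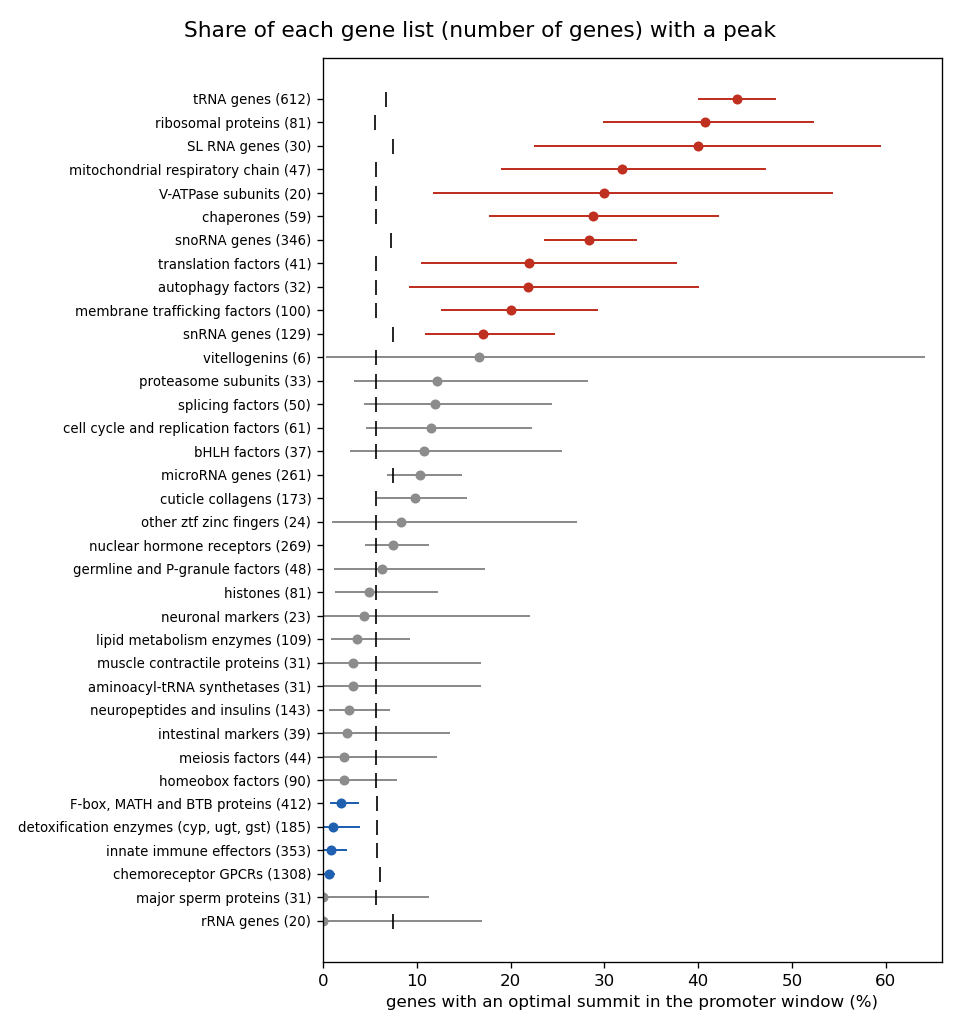
Percent of the genes of each list with an optimal summit in their promoter window (x axis), with points for the list, horizontal bars for the 95% exact interval and black ticks for the other genes of the background. Red marks the 11 lists above and blue the 4 below the background at an adjusted p under 0.05, from 44.1% of tRNA genes to 0.612% of chemoreceptor genes.

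The sequence at summits differed from that 300 bp away. Summit windows were richer in G and C (46.3% against 35.7%). Of 8187 words of 7 bases tested, 264 passed on chromosomes I, III and V, and 174 of these passed again on the held-out II, IV and X. A group of overlapping words led by ACGCAGA, CTGCGTC and GAGACGC was found in 6.79%, 6.97% and 7.07% of held-out summit windows, against 0.848%, 1.04% and 1.23% of flanks (McNemar's exact test, adjusted p = 2.6e-11, 7.7e-11 and 4.1e-10). Runs of alternating C and T came next, with CTCTCTC in 9.05% of held-out summits and 2.36% of flanks (adjusted exact p = 1.5e-09). The words CACGTGA (4.34% against 0.754%) and CACGTGG (3.96% against 0.66%), which contain the E-box core CACGTG, also passed, as did CGCCAGC (3.39% against 0.189%, adjusted exact p = 1.6e-07).

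The words differed in where they were found. GGTTCGA is part of the internal B box of tRNA genes, so windows on these genes hold it by their own sequence, and 74 of the 95 summits with it lay within 100 bp of a tRNA gene. GAGACGC was found at 1 of the 210 summits within that distance and 159 of the 1719 others. It was rarer on X than on the autosomes (3.67% against 9.75%, Fisher's exact test, adjusted p = 8.2e-05). The adjustment covered 36 comparisons of words and places, chosen after the words were known. GGTTCGA was more frequent on X (8.42% against 3.82%, adjusted exact p = 0.00053). The contrast of GAGACGC between X and autosomes was not tested without the peaks near tRNA genes, so the 2 are not separated. CGCCAGC was found at 5.70% of summits in promoter windows and 1.37% of others (adjusted exact p = 2.6e-06), whereas GAGACGC did not pass that comparison (9.05% against 7.51%, adjusted exact p = 0.39). The count of 174 depended on the peaks used, with 77 words past both steps without replicate 3 and 59 with the 965 strongest peaks.

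**Figure D4:**
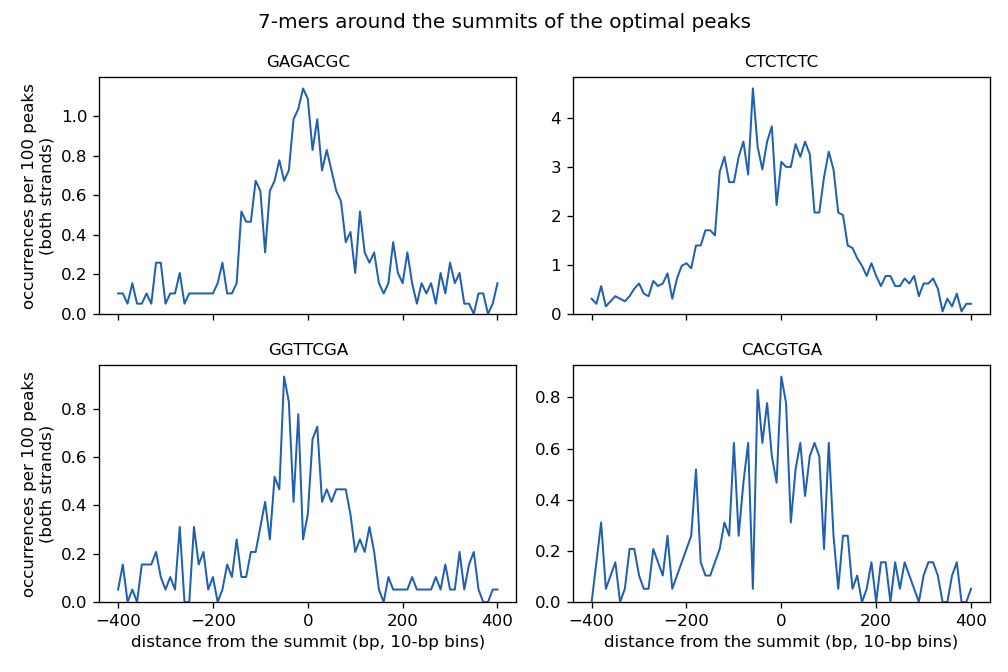
Occurrences of 4 words per 100 optimal peaks on either strand (y axes, overlapping matches counted, a scale for each panel) by distance from the summit (x axis, bp, in 10-bp bins). The highest bin of each word lay at most 60 bp from the summit. CTCTCTC formed a broad plateau, from the bin at -130 bp (2.90) to that at 110 bp (2.95). GGTTCGA was lower at the summit (0.36) than in the bin at -50 bp (0.93).

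Neither the tagged gene nor unc-119 had an optimal peak. No optimal peak lay within 5000 bp of ztf-26 (I:8853589-8861278), the tagged gene, and the pooled and replicate lists used here also held no candidate there. The interval without candidates was unusually long, at 65400 bp in the pooled list, so it is not read as a measured lack of binding. Around unc-119 (III:10902641-10908935), which is mutated in the strain per its genotype, there was no optimal peak, and the 3 pooled candidates reached a signal of 26.1.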

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

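The direction and side of the threshold of the replicate overlap, the promoter share and the X share held under the alternatives tried for each. The overlap ran from 61.4% (at least 50% of both peaks shared) to 73.1% (the 965 strongest peaks), the promoter share from 41.1% to 64.1% with narrower and wider windows, and the X share from 23.3% to 24.1%. The number of gene lists past the threshold was 11 to 18, and each replicate alone gave 15. The ce10 build gave 1904 optimal peaks. The stricter list held 965 peaks by construction. Spearman's rho fell from 0.635 to 0.605 when summits had to lie within 100 bp, just outside its interval of 0.606 to 0.662, and the cause was not tested. The count of 7-mers was the least stable value. It was 59 with the 965 strongest peaks, where fewer peaks were tested, 37 with 25 bp either side of the summit, where windows were shorter, 298 for words of 6 bases and 39 for words of 8 bases, where the number of words tested differed, and 77 to 193 with each replicate alone, for which the cause was not tested. Of the 174, 68.4% were shared without replicate 4, 35.6% without replicate 3, 27.6% with the 965 strongest peaks and 20.7% with the shorter window, and overlapping words of the group ACGCAGA and CTGCGTC led in each setting except the 965 strongest peaks, where CGAGAGA led. For the 15 called lists, 82 alternative values kept their call and 8 lost it, each given with its list. Of the 25 top peaks, 22 ranked among the top 25 without replicate 3 and 23 without replicate 4, with fbxb-58, T04C4.3 and tag-340 outside in replicate 4 and ftt-2 and egg-5 outside in replicate 3. No paired analysis was possible because the samples form 1 group. Depth is unknown, so how far it limits the weaker candidates was not measured.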

Other observations

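The tests of a single replicate for the X excess, of the motif outside the strongest peaks and of high transcription were chosen after the result was seen, and the idea of the X-linked motif came from the positions of the strongest X peaks. A 12-base sequence, TCGCGCAGGGAG, is the consensus of the MEX motif, known from sites on X where the worm dosage compensation complex is recruited. With up to 2 mismatches and within 100 bp of the summit, it was found at 25 of 463 optimal peaks on X (5.40%) and 9 of 1466 on autosomes (0.614%), while 0.662% of lower-ranked X candidates and 0.467% of random placements had it. Among the top 25 peaks it was found at 11 of the 15 on X and at 0 of the 10 on autosomes, and 15 of the 50 strongest X peaks had it, against 10 of the other 413 (2.42%). The 25 X peaks with a match had a median signal of 537, against 127 for the other 438, and 4 of them (16.0%) were in a promoter window against 41.8% of the others (Fisher's exact p = 0.011). Neither comparison is independent of the choice of motif. The top X peaks prompted the idea, were mostly outside promoter windows, and include 11 of the 25.

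For the excess of optimal peaks on X, sites with the MEX motif are a candidate explanation of the strongest peaks, since the odds ratio of a match on X against autosomes was 9.24 (Fisher's exact p = 1.1e-09), but those peaks prompted the idea. Among peaks weaker than the 50 strongest on X it was 4.15 (10 of 413 against 8 of 1346, Fisher's exact p = 0.0032). Peaks holding a match by this rule do not account for the whole excess. Without them X still took 23.1% of optimal and 16.6% of lower-ranked peaks (odds ratio 1.51, Fisher's exact p = 3.8e-12). Only 25 of the 463 optimal X peaks held a match, so leaving them out could not remove the excess. Sites with a weaker or more distant match were not tested. The X share without peaks near tRNA genes was not computed either, so their part in the excess is unknown. GGTTCGA, mostly found near these genes, was at 39 of 463 X and 56 of 1466 autosomal optimal summits. A single replicate as the source is argued against, since the smaller of the odds ratios in the replicates' own lists was 1.42 (Fisher's exact p = 2.0e-09). Whether ZTF-26 itself is at these sites, or open X chromatin that an anti-GFP library of any factor would recover, stays open without such a library.

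The peaks at tRNA, snoRNA and ribosomal protein genes could come from ZTF-26 or from signal at strongly transcribed genes. For ribosomal protein genes, the mere presence of a candidate is argued against as the whole source. Among genes with a candidate summit they still had an odds ratio of 5.12 (Fisher's exact p = 1.3e-10). It was 11.7 against all other protein-coding genes, so part of the excess went with the presence of a candidate. The number of candidates at each gene was not compared. High transcription in general stays open, since of 7 lists of genes with abundant products (47 of 296 genes with a peak, 15.9%) some passed and some did not, with chaperones, the respiratory chain and translation factors above other genes and vitellogenins, major sperm proteins, histones and muscle contractile proteins not past the threshold. A candidate of any rank was listed at 4 of 6, 6 of 31, 25 of 81 and 15 of 31 genes of these last lists, so the sperm protein and histone genes bear little weight, and of the 15 muscle genes 1 had an optimal peak. Signal that any immunoprecipitation gives at these genes cannot be told apart from binding, since the samples hold 0 libraries without the fusion protein or of another factor.

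For the 7-mers, base composition as the whole cause is argued against, since the 264 words past the step on chromosomes I, III and V exceeded other words of the same composition by a median of 0.76 in log2 ratio on the held-out chromosomes, which did not enter their choice (95% bootstrap interval 0.62 to 0.87). Summits in tRNA genes are argued against as the main source, since 144 words passed both steps without the 210 peaks near tRNA genes, although 73 of the 174 were lost (58% were kept). The group GAGACGC and ACGCAGA may be a motif of ZTF-26 or of a factor that shares its sites, and no test here separates these. The design holds 1 group, so no biological difference between groups could be tested for these patterns.

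The interval without candidates around ztf-26 was long in each list used here. It measured 65400 bp in the pooled list, where 16 of 23437 gaps were as long and the median was 1459 bp, 63799 bp in replicate 3 and 65194 bp in replicate 4. A gap in each list can arise in processing, so it is not evidence that ZTF-26 does not bind there.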
